A study of Rattus norvegicus with 36 samples.

How the data were processed

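The series holds 36 arrays of kidney RNA from Sprague Dawley rats, 1 rat per array, read on a rat 4x44K design with 1 colour (Cy3). Groups were taken from the labels: predose saline, gentamicin days 2, 4, 8 and 15, and recovery day 29, each with 3 female and 3 male rats. The labels of the day 2 males disagree in 1 field, whose text names females, while title and source name males, and these arrays were kept as males. By Y-linked genes 0 of 36 arrays failed to match the sex of their group. The series text gives 80 mg/kg each day for 28 days followed by 28 days of recovery, and the labels do not say from which day recovery day 29 is counted. The replicate number was checked as a link between rats of different groups. The mean correlation between arrays of the same number was -0.007, so groups were treated as independent and replicates are the labels' separate samples.

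Per the file headers the scanner files were written by Agilent Feature Extraction 10.7, and their processed signal is an intensity on the linear scale, background-subtracted and detrended within each array, with no scaling between arrays. The deposited median spot and background signals are raw scanner intensity values, and the deposited flags for signal well above background, saturation and outliers have values of 0 or 1 in another unit (other). The authors also deposited a table of log2 values whose columns share 1 distribution, as quantile normalization gives. The text of the series does not state how that table was made, and it was used only as an alternative. The scanner files hold no mean signal, so the planned normexp correction was run on the median signal.

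Values were log2 of the processed signal minus the 75th percentile of the array. Spots flagged as outliers were left out (128 probe values) and no probe was saturated. Of 41012 probes, 17541 were given a gene symbol through their RefSeq accession and the reference gene table, and 23471 had none and were tested only as an alternative. Probes well above background on at least 3 of 36 arrays were kept (30226, of which 14178 with a symbol). Of several probes of a gene the one with the highest mean signal stood for it, giving 10977 genes, 2597 of them with several kept probes. Among genes called at day 15 with several probes, 121 of 1107 had a probe of opposite sign, and in 13 that probe passed as well. At day 4 these numbers were 229 of 1186 and 50. The tables used hold no coordinates, so no positions are given.

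A model with 1 mean for each of the 12 groups was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 24 residual and 3.04 prior degrees of freedom). Tests are 2-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Each time was compared with predose for both sexes together (the mean of the female and male change) and for each sex. Successive times were compared for both sexes together, the change was compared between the sexes, and the sexes were compared at predose. Gene lists were written beforehand (42 lists, 659 entries, 557 measured) and tested with limma camera at a preset correlation of 0.01 and with an estimated one, for lists with at least 4 measured members. A gene well above background on no array of the dimmer groups has only a bound there. It is given as "at least", from the mean of the brighter groups against the mean of the higher of the lowest signal well above background and the probe's own signal on each dim array. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

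Genes were named by a rule. It took the 8 largest rises and the 8 largest falls of each day, and of recovery day 29 against day 15, among called genes with the same sign in both sexes and signal on all 3 arrays of a group. It added up to 4 members of each list with the lowest adjusted p, a panel of 23 kidney genes, and the 5 largest differences each way between the sexes. Of the panel Mki67 and Top2a were not measured. The groups, comparisons, tests, lists, naming rule and most alternatives were set before the data were examined.

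Alternatives were quantile normalization, the authors' log2 table, normexp with an offset of 50, no filter on dim probes, only probes well above background on all 36 arrays, the mean of the probes, eBayes with trend and robust settings, a fit to the compared groups alone, replicate number, slide or scan date as a block, and leaving out each array. Targets without a symbol and the removal of 2 arrays of weak signal were added after seeing the data. Arrays lay on 10 slides and 3 scan days. The first scan day held 5 predose arrays, the next held replicate 3 of the predose females with days 2, 4 and 15, and the last held day 8 and recovery day 29. The pipeline was tested on simulated data with changes of known size. At day 15 it recovered 52.2% of genes changed 1.5-fold, 86.6% of those changed 2-fold and 98.5% of those changed 4-fold with both sexes together, with 3.66% false calls. For the difference between the sexes it recovered 11.9, 26.9 and 80.3%, with 7.06% false calls. Few genes were changed in the simulation, 67, 67 and 66 at the 3 sizes. Its noise was independent between genes, with 1 spread per gene in all groups and no effect of slide or scan date. These shares therefore describe that setting and are not error rates of the real comparisons. The number of arrays limits the precision.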

Results

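Kidney RNA from Sprague Dawley rats was measured on 36 single-colour arrays, 1 rat per array, in 12 groups of 3. The groups cross sex with 6 sampling times. Predose rats had received saline, the rats of days 2, 4, 8 and 15 had received 80 mg/kg gentamicin each day into the muscle, and the last groups were sampled at recovery day 29. Gentamicin is an aminoglycoside antibiotic that cells of the proximal tubule take up from the filtrate. No saline group was sampled after predose, so time in the study and age moved with treatment in every comparison with predose. Between 52.8 and 67.7% of the 41012 probes lay well above background on an array. The 75th percentile of the signal ran from 156 to 472 intensity units, lowest on replicate 3 of the day 4 males, and the number of arrays limits the precision. After filtering, 10977 genes with a symbol were tested. Changes are given as the mean of the female and the male change, with limma's standard error and n = 6 rats per time point, unless a single sex is named.

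The first comparison asked which kidney genes had changed by day 2, 24 hours into dosing. Interferon response genes rose together: 15 of 17 measured members were higher, 17 when adjusted over the list alone, with a median log2 change of 1.83. Among them Isg15, an ubiquitin-like protein induced by interferon, was 6.14-fold higher (2.62 ± 0.22 log2, adjusted p = 4.9e-09) and Mx1, an antiviral GTPase, rose by 2.38 ± 0.24 log2. Of 18 cytokine and chemokine genes 9 rose and none fell, 15 when adjusted over the list alone. The neutrophil chemokine Cxcl1 was 8.44-fold higher (3.08 ± 0.27 log2, adjusted p = 9.6e-09) and the monocyte chemokine Ccl2 was 2.22-fold higher. Of 18 tubular injury markers 9 rose and none fell, 14 when adjusted over the list alone. The kidney injury molecule Havcr1 was 4.17-fold higher (2.06 ± 0.38 log2, adjusted p = 0.0011), osteopontin (Spp1) 2.56-fold and Lcn2, a carrier of bacterial siderophores, 2.13-fold. These lists passed limma camera, which sets the members against all other genes. The adjusted p values were 1.6e-42 for interferon genes, 7.0e-18 for cytokines and 1.2e-16 for injury markers. With an estimated correlation the adjusted p values were 0.00058, 0.00054 and 0.0033.

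At day 2 Atf3, a stress-induced transcription factor, was 11.3-fold higher (3.50 ± 0.28 log2, adjusted p = 1.3e-09) and Gadd45b, induced by growth arrest and DNA damage, 11.7-fold. The neuropeptide precursor Vgf was at least 6.17-fold higher and the natriuretic peptide Nppc at least 5.27-fold higher, both being well above background on no predose array. Endothelin 1 (Edn1), a vasoconstrictor peptide, was 6.59-fold higher and well above background on 4 of 6 predose arrays. Of 17 genes of the unfolded protein and integrated stress response 5 rose, 10 when adjusted over the list alone, including Ddit3 (1.25 ± 0.20 log2) and Atf4 (1.14 ± 0.15 log2). This list passed camera at adjusted p = 8.9e-12, and at adjusted p = 0.034 with an estimated correlation. Some genes of the collecting duct were lower. Of 9 principal cell markers 3 fell, 5 when adjusted over the list alone, among them the sodium channel subunit Scnn1g (-0.66 ± 0.13 log2) and Hsd11b2, which inactivates glucocorticoids (-0.66 ± 0.13 log2). Of 9 intercalated cell markers 2 fell, 4 when adjusted over the list alone, including the anion exchanger Slc4a1 (-0.89 ± 0.18 log2, adjusted p = 0.0038). The water channel Aqp6 of the same cells fell by 1.03 ± 0.22 log2, by 0.19 log2 in females and 1.87 log2 in males. Camera called both lists, at adjusted p = 4.2e-05 for principal and 1.0e-05 for intercalated cells, and at adjusted p = 0.0199 and 0.0341 with an estimated correlation. No proximal tubule transporter and no gene of megalin and cubilin uptake passed the test. Lrp2 (megalin) changed by -0.13 ± 0.16 log2 and Cubn by -0.25 ± 0.20 log2.

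In all, 292 genes passed at day 2, 218 higher and 74 lower. With scan date as a block, an estimate that rests on the 1 predose female array scanned with these groups, 21 genes passed, the interferon list kept a median of 1.20 and the injury list one of 0.48, the intercalated cell list one of -0.14, and Havcr1 (1.27 log2) and the principal cell list (median -0.16) no longer passed. Normexp background correction called 53 genes, all among the 292, and leaving out replicate 3 of the day 2 females called 179.

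By day 4 the question was how far the early change had spread. Genes of the unfolded protein and integrated stress response rose in 15 of 17 cases and none fell, with a median log2 change of 1.02. Derl3, which moves misfolded proteins out of the endoplasmic reticulum, was 11.4-fold higher (3.51 ± 0.29 log2, adjusted p = 1.6e-09), the chaperone partner Sdf2l1 6.22-fold, Ddit3 5.14-fold and Atf4 4.07-fold. Atf3 was 27.2-fold higher (4.77 ± 0.28 log2, adjusted p = 1.5e-12). Of 13 immediate early genes 11 rose and 1 fell, with Fos at 8.52-fold. The interferon list again had 15 of 17 members higher, 17 when adjusted over the list alone (median 1.63). Of 17 p53 targets 13 rose and none fell, including Plk2 at 8.47-fold and the cell cycle inhibitor Cdkn1a at 5.53-fold (2.47 ± 0.26 log2). Cell cycle genes also rose, 20 of 23 members, 21 when adjusted over the list alone, but by less, with cyclin genes Ccnb1 and Ccna2 at 2.15-fold and 2.11-fold. Of 18 injury markers 13 rose and none fell, and Havcr1 stood at 6.44-fold (2.69 ± 0.38 log2, adjusted p = 6.3e-06).

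Genes of protein synthesis were higher at day 4 as well. Of 23 cytosolic ribosomal protein genes 19 rose, 21 when adjusted over the list alone, with a median log2 change of 0.61 (0.28 under quantile normalization and 0.32 in the authors' table) and Rpl4 at 1.99-fold. The endocytic receptors of the proximal tubule had now fallen, Lrp2 by 1.00 ± 0.16 log2 and Cubn by 1.04 ± 0.20 log2, yet of the 13 genes of that list 4 rose and 5 fell, so its median was -0.06 and camera did not call it (adjusted p = 0.0855). Of 9 principal cell markers 6 fell and 1 rose, including Scnn1g (-1.02 ± 0.13 log2) and the transcription factor Gata3 (-1.04 ± 0.13 log2). Of 13 clock genes 3 rose and 8 fell (camera adjusted p = 0.0365, and adjusted p = 0.38 with an estimated correlation), a call that quantile normalization and scan date as a block each ended. Bmal1, a core activator of the circadian clock, was 9.28-fold higher (3.21 ± 0.15 log2, adjusted p = 3.4e-14), while the clock repressor Per2 fell by 1.99 ± 0.21 log2 and Dbp by 1.53 ± 0.16 log2. Camera called the interferon (adjusted p = 1.1e-09), unfolded protein (8.7e-09), immediate early (9.0e-05), cell cycle (9.0e-05), injury (0.00011), ribosomal (0.00014), p53 (0.00031) and principal cell lists (0.00053). None of them held with an estimated correlation, where the lowest adjusted p was 0.214.

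In all 4800 genes passed at day 4, 3309 higher and 1491 lower, and the median over all genes was 0.15. Quantile normalization lowered that median to 0.08 and normexp to 0.05. The balance held for genes with a symbol only. Of 15084 targets without one, 2013 were higher and 3746 lower at day 4, with a median of -0.09. Signal was weakest at this time, with 52.8 to 60.0% of probes well above background, and the spread within the day 4 males was the widest of the 12 groups (median SD 0.40). With scan date as a block 96 genes passed and the unfolded protein list kept a median of 0.95. In that fit Atf3 and Cdkn1a passed. Havcr1, Lrp2 and Slc34a1 had log2 changes of 1.90, -0.77 and -0.60 and did not pass (adjusted p = 0.258, 0.291 and 0.319), and normexp called 2012 genes.

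**Figure D1:**
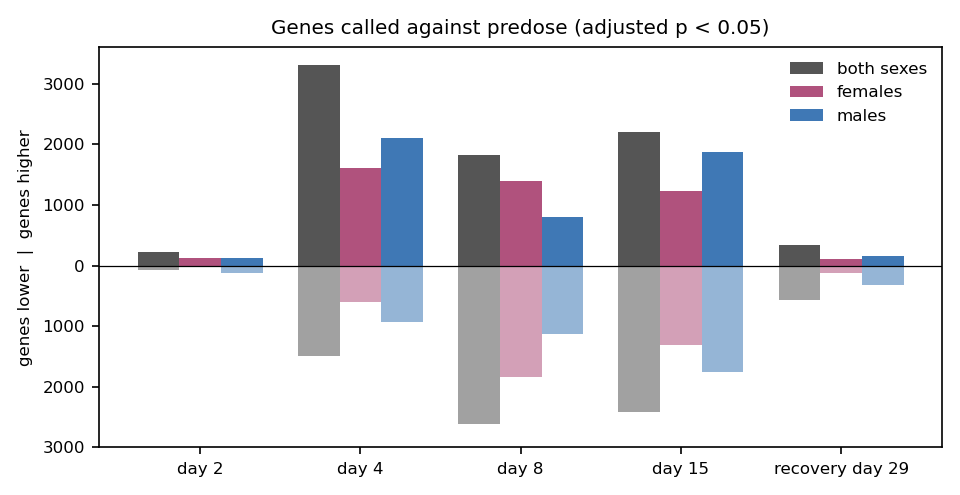
Number of genes past the test (adjusted p below 0.05, limma) at each time against predose, with genes that were higher drawn above 0 and genes that were lower drawn below, for both sexes together, females and males. The count for both sexes rose from 292 at day 2 to 4800 at day 4 and stood at 902 at recovery day 29.

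At day 8 metabolic and transport genes of the proximal tubule fell. Of 24 genes of fatty acid oxidation 20 fell and 2 rose, 21 and 2 when adjusted over the list alone, with a median log2 change of -0.80. The thiolase Acaa2 fell by 1.71 ± 0.15 log2 (adjusted p = 1.9e-09). Of 10 genes of gluconeogenesis and ammoniagenesis 6 fell and none rose, among them Pck1 (-1.97 ± 0.16 log2) and Glud1 (-1.27 ± 0.09 log2). Of 23 proximal tubule transporters 14 fell and 1 rose. The amino acid exchanger subunit Slc7a7 fell by 1.54 ± 0.18 log2, the water channel Aqp1 by 1.03 ± 0.12 log2, the organic anion transporter Slc22a6 by 1.04 ± 0.24 log2 and the phosphate transporter Slc34a1 by 0.85 ± 0.13 log2. Oxidative phosphorylation genes fell in 12 of 24 cases and none rose.

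Genes of the p53 response and the cell cycle were higher than predose at day 8. Cdkn1a was 25.5-fold higher (4.67 ± 0.26 log2, adjusted p = 6.8e-13), and 13 of 17 p53 targets rose and 1 fell, 14 and 1 when adjusted over the list alone, including Plk2 at 9.66-fold, the death receptor Fas at 4.63-fold and the apoptosis effector Bbc3 at 3.83-fold. Of 23 cell cycle genes 20 rose and 1 fell, with the nucleotide reductase subunit Rrm2 at 4.04-fold. Havcr1 reached 33.4-fold (5.06 ± 0.38 log2, adjusted p = 1.4e-10). Fosl1, a subunit of the AP-1 transcription factor, was 57.9-fold higher and well above background on 2 of 6 predose arrays. The drug efflux pump Abcb1b was 14.0-fold higher. Of 18 cytokine genes 14 rose and 1 fell, with Cxcl1 at 8.35-fold, Cxcl10 at 7.39-fold and Ccl2 at 6.92-fold. Markers of other cell types moved too. Of 12 T cell markers 7 rose, such as Cd3g at 3.04-fold, with a list median of 1.02, while 4 of 5 erythrocyte markers fell, 5 when adjusted over the list alone, with a median of -2.15.

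By camera these day 8 lists passed, with adjusted p = 1.1e-12 for the interferon list, 6.6e-11 for the cell cycle, 5.1e-10 for p53 targets, 1.2e-09 for fatty acid oxidation and 0.0011 for proximal tubule transporters. With an estimated correlation cytokines (adjusted p = 0.0093), p53 targets (0.0495), fatty acid oxidation (0.0495) and gluconeogenesis (0.0495) held. The cell cycle (adjusted p = 0.0905), interferon (0.0778), transporter (0.0991), oxidative phosphorylation (0.518), T cell (0.195) and erythrocyte lists (0.262) did not. In all 4433 genes passed, 1823 higher and 2610 lower. No predose array was scanned with day 8, so these values hold any effect of scan date. Recovery day 29 was scanned with it, and recovery day 29 minus day 8 gave medians of 0.756 for fatty acid oxidation, 0.682 for transporters, -1.004 for p53 targets and -2.53 for the cell cycle. With an estimated correlation these lists passed at adjusted p = 0.03765, 0.03765, 0.03765 and 0.0089. The cell cycle list lay below predose at recovery day 29, so its median of -2.53 also holds that fall. The T cell list gave a median of -0.0985 there (camera adjusted p = 0.666), so for T cell markers scan date and day 8 cannot be told apart. Normexp called 1885 genes, moved the T cell list to a median of -0.03 and ended the calls of the T cell, transporter and oxidative phosphorylation lists, the last of which quantile normalization ended too.

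Day 15 was compared with predose for the effect of longer dosing. Havcr1 was 184-fold higher than at predose (7.52 ± 0.38 log2, adjusted p = 4.5e-14), the largest of the named rises. Of 18 injury markers 15 rose and 1 fell, 16 and 1 when adjusted over the list alone, with a median log2 change of 1.87. Spp1 was 18.4-fold higher (4.20 ± 0.26 log2), Lcn2 11.2-fold (3.49 ± 0.17 log2, adjusted p = 4.5e-14), the protease inhibitor Timp1 3.80-fold and the chaperone clusterin (Clu) rose by 1.59 ± 0.16 log2. The acute phase protein Serpina3n was 44.5-fold higher (5.48 ± 0.54 log2). Il24, a cytokine of the interleukin 10 family, was 56.4-fold higher and well above background on 2 of 6 predose arrays, and Il1rl1, the receptor of interleukin 33, was 53.4-fold higher by 1 probe (5.74 log2), well above background on 1 of 6, and 2.56 log2 higher by the other. Cell cycle genes now moved as a block: 22 of 23 rose, with a median of 2.28, cyclin Ccna2 at 7.70-fold (2.95 ± 0.21 log2) and the replication licensing factor Mcm3 at 5.74-fold.

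Immune genes rose as well at day 15. All 17 interferon genes were higher (median 2.48), with Isg15 at 12.5-fold, and 16 of 18 cytokine genes rose. Complement genes rose in 13 of 14 cases, such as C2 at 5.95-fold and C1qb at 2.80-fold. Markers of T cells rose in 11 of 12 cases, such as Cd3g at 5.22-fold. Markers of macrophages rose in 10 of 12, all 12 when adjusted over the list alone, such as Cd68 at 3.18-fold. Antigen presentation genes rose in 11 of 14 cases, such as the immunoproteasome subunit Psmb8 at 4.82-fold. Of 19 matrix genes 12 rose and 1 fell, 13 and 2 when adjusted over the list alone, with a median of 0.49 and fibronectin (Fn1) at 0.52 ± 0.15 log2.

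Tubular genes were also below predose at day 15. Of 24 fatty acid oxidation genes 20 fell and 1 rose, 21 and 1 when adjusted over the list alone. The peroxisomal thiolase Acaa1b fell by 3.21 ± 0.21 log2 (adjusted p = 3.2e-12) and the bifunctional enzyme Ehhadh of the same pathway by 2.06 ± 0.20 log2. Of 23 proximal tubule transporters 15 fell and 1 rose, including the phosphate transporters Slc34a3 (-1.87 ± 0.16 log2) and Slc34a1 (-1.19 ± 0.13 log2) and the organic cation transporter Slc22a2 (-1.26 ± 0.20 log2). Of 13 genes of megalin and cubilin uptake 9 fell and 1 rose, 11 and 1 when adjusted over the list alone, with Lrp2 at -0.85 ± 0.16 log2, Cubn at -0.92 ± 0.20 log2 and the cubilin partner Amn at -0.73 ± 0.09 log2. All 9 intercalated cell markers fell, with a median of -1.22, including the anion exchanger pendrin (Slc26a4, -1.65 ± 0.15 log2) and the ammonia transporter Rhbg (-1.34 ± 0.14 log2). Epidermal growth factor (Egf), made in the distal nephron, fell by 1.48 ± 0.19 log2. All 5 erythrocyte markers fell, with a median of -3.31, among them the globin gene Hbb (-3.45 ± 0.37 log2) and Alas2, the control enzyme of haem synthesis in red cells (-3.62 ± 0.41 log2). Cyp1a1, a target of the aryl hydrocarbon receptor, fell by 4.02 ± 0.52 log2 and was well above background on 2 of 6 day 15 arrays.

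With camera the day 15 lists passed at adjusted p = 8.4e-18 for the cell cycle, 3.8e-16 for interferon, 9.7e-15 for injury markers, 1.3e-10 for fatty acid oxidation, 1.5e-06 for intercalated cells and 4.6e-05 for proximal tubule transporters. With an estimated correlation these held at adjusted p = 0.0236, 0.0236, 0.0111, 0.0236, 0.0236 and 0.0236 in the same order. Cytokines (adjusted p = 0.0111), complement (0.0311), T cells (0.0392), macrophages (0.0353) and megalin and cubilin uptake (0.0236) also held. Antigen presentation (adjusted p = 0.0916), matrix (0.303) and erythrocytes (0.0930) did not. In all 4630 genes passed, 2211 higher and 2419 lower, 842 of them at least 2-fold higher and 462 at least 2-fold lower. With scan date as a block, resting on 1 predose female array, 1340 genes passed, Havcr1 kept a log2 change of 6.73 and the injury, cell cycle and fatty acid oxidation lists medians of 1.71, 1.75 and -0.97, while the matrix list no longer passed. Normexp called 2099 genes and ended the call of the list of megalin and cubilin uptake.

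**Figure D2:**
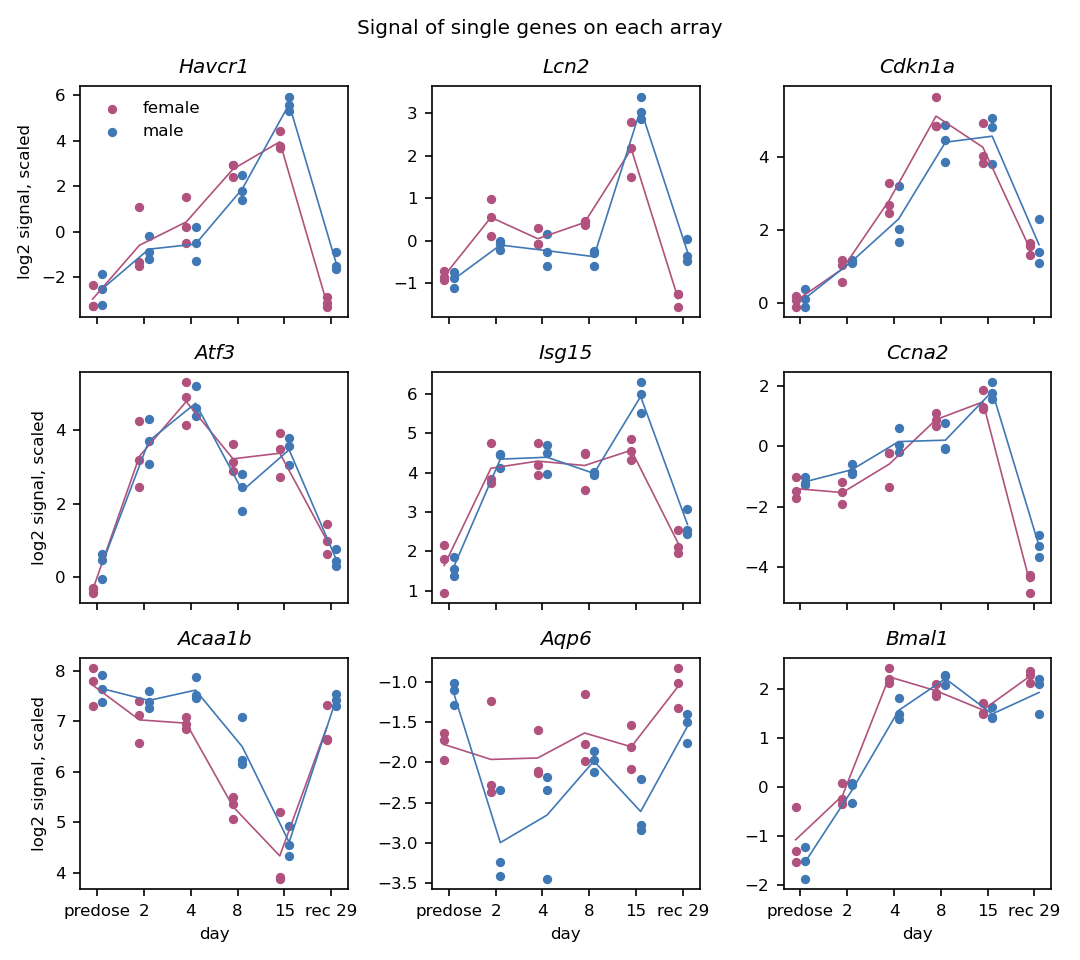
Log2 signal relative to the 75th percentile of the array for 9 named genes at each sampling time, with 1 point per array (3 females and 3 males per time) and a line through the mean of each sex. Havcr1, Lcn2 and Ccna2 were highest at day 15 and Acaa1b was lowest there. Bmal1 was above predose at each later time, by least at day 2. There the lowest array had -0.35, beside -0.40 on the 1 predose array scanned that day.

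Recovery day 29 was set against predose to see what remained after dosing had ended. With both sexes together Havcr1 differed by 0.52 ± 0.38 log2 (adjusted p = 0.479), Lcn2 by 0.06 ± 0.17 log2 and Timp1 by 0.02 ± 0.16 log2, and 3 of 18 injury markers passed, all higher. Among them Spp1 was 2.65-fold higher (1.41 ± 0.26 log2). By sex, Lcn2 changed by -0.53 log2 in females and 0.65 log2 in males, Havcr1 by -0.14 and 1.18 log2 and Spp1 by 0.76 and 2.05 log2, and none of these 3 differences passed in limma (adjusted p = 0.4855, 0.8925 and 0.8077, unadjusted p = 0.0017, 0.092 and 0.0197). Beside them the p53 target Cdkn1a was 2.75-fold higher (1.46 ± 0.26 log2, adjusted p = 0.00054). Of 23 proximal tubule transporters 1 was higher and 1 lower (median 0.0078, camera adjusted p = 0.361). Slc34a1 changed by 0.01 ± 0.13 log2, Lrp2 by 0.07 ± 0.16 log2 and Cubn by -0.02 ± 0.20 log2 (0.34 in females and -0.38 in males). Fatty acid oxidation genes passed in 3 of 24 cases, all lower. T cell markers were higher in 7 of 12 cases, 9 when adjusted over the list alone, with a median of 0.80 (0.25 under normexp) and Cd3g at 2.99-fold. Complement genes were higher in 5 of 14 cases, 6 when adjusted over the list alone, including complement factor I (Cfi) at 2.25-fold. The interleukin gene Il1b was 2.89-fold higher and Ccl2 2.36-fold.

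Cell cycle genes had dropped below predose at recovery day 29. Of 23 members 17 were lower and none higher, 18 when adjusted over the list alone, with a median log2 change of -1.30. The mitotic cyclin Ccnb2 fell by 3.00 ± 0.23 log2 and was well above background on 3 of 6 recovery arrays, the mitotic kinesin Kif20a fell by 2.82 ± 0.23 log2 (adjusted p = 1.6e-09), and the mitotic kinase Pbk was at least 4.83-fold lower. Matrix genes were lower too, in 8 of 19 cases with 1 higher, 9 and 2 when adjusted over the list alone, with Col3a1 at -1.06 ± 0.21 log2 and Fn1 at -0.88 ± 0.15 log2. Of 13 clock genes 2 were higher and 5 lower, and camera did not call the list (adjusted p = 0.116). Bmal1 was 10.6-fold higher (3.40 ± 0.15 log2, adjusted p = 7.9e-15) and the clock gene Npas2 5.82-fold (its other probe 1.13 log2). Dbp fell by 2.65 ± 0.16 log2 and Per3 was at least 4.50-fold lower (its other probe -1.62 log2). By camera the cell cycle list passed at adjusted p = 2.3e-29, T cells at 1.9e-08, complement at 2.3e-06 and matrix at 0.0079. With an estimated correlation only the cell cycle held of these 4 (adjusted p = 0.0066, against 0.111, 0.216 and 0.598). In all 902 genes passed, 341 higher and 561 lower. Scan date and recovery cannot be told apart against predose, since the recovery arrays were scanned on a day with no predose array. Normexp called 76 genes, all among the 902.

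Recovery day 29 was also set against day 15, to ask what had turned back. Havcr1 was 128-fold lower (-7.00 ± 0.38 log2, adjusted p = 2.1e-14), Lcn2 fell by 3.43 ± 0.17 log2 and Cdkn1a by 2.87 ± 0.26 log2. Of 18 injury markers 15 fell and none rose, 16 when adjusted over the list alone, and all 17 interferon genes fell. Of 23 cell cycle genes 22 fell and none rose, with a median of -3.87 and Ccna2 at -5.56 ± 0.21 log2. Fatty acid oxidation genes rose in 20 of 24 cases and fell in 1, 21 and 1 when adjusted over the list alone, with Acaa1b at 6.39-fold (2.68 ± 0.21 log2). Proximal tubule transporters rose in 14 of 23 cases and fell in 1, 19 and 2 when adjusted over the list alone, and all 9 intercalated cell markers rose, with Slc26a4 at 2.61-fold. Slc34a1 rose by 1.20 ± 0.13 log2, Lrp2 by 0.92 ± 0.16 log2 and Cubn by 0.90 ± 0.20 log2. Of 12 T cell markers 8 fell (median -0.79). Camera called the injury (adjusted p = 1.2e-14), interferon (1.8e-13), cell cycle (2.6e-29), fatty acid oxidation (1.1e-10), transporter (1.5e-06), intercalated cell (1.9e-06) and T cell lists (0.0038). All held with an estimated correlation, at adjusted p = 0.0093, 0.0397, 0.0067, 0.0219, 0.0171 and 0.0219, except the T cell list at adjusted p = 0.253. In all 4168 genes passed, 1955 higher and 2213 lower. These groups were scanned on different days, so their difference holds any effect of scan date. Against day 8, scanned with recovery day 29, that group was lower in 10 of 18 injury markers and higher in 1 (median -0.676) and lower in 13 of 17 interferon genes (median -0.949). Camera called these lists at adjusted p = 4.7e-05 and 5.1e-08, and not with an estimated correlation (adjusted p = 0.179 and 0.1805). Normexp called 1889 genes and moved the T cell list to a median of -0.09.

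The calls at recovery day 29 and day 15 overlapped. Of the 902 genes 503 were also called at day 15 in the same direction, 225 higher and 278 lower, and 139 in the opposite one. Independent lists of these sizes would share 192.3 in the same direction. Both comparisons use the predose arrays, so they were also set against different predose arrays: over 18 splits of the predose arrays, 149.2 genes were shared on average (126 to 192), where independent lists would share 48.97. In every split most predose arrays came from a scan day of their own, which held 5 of the 6, so any offset of that day enters both comparisons. Normexp shared 43 genes.

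**Figure D3:**
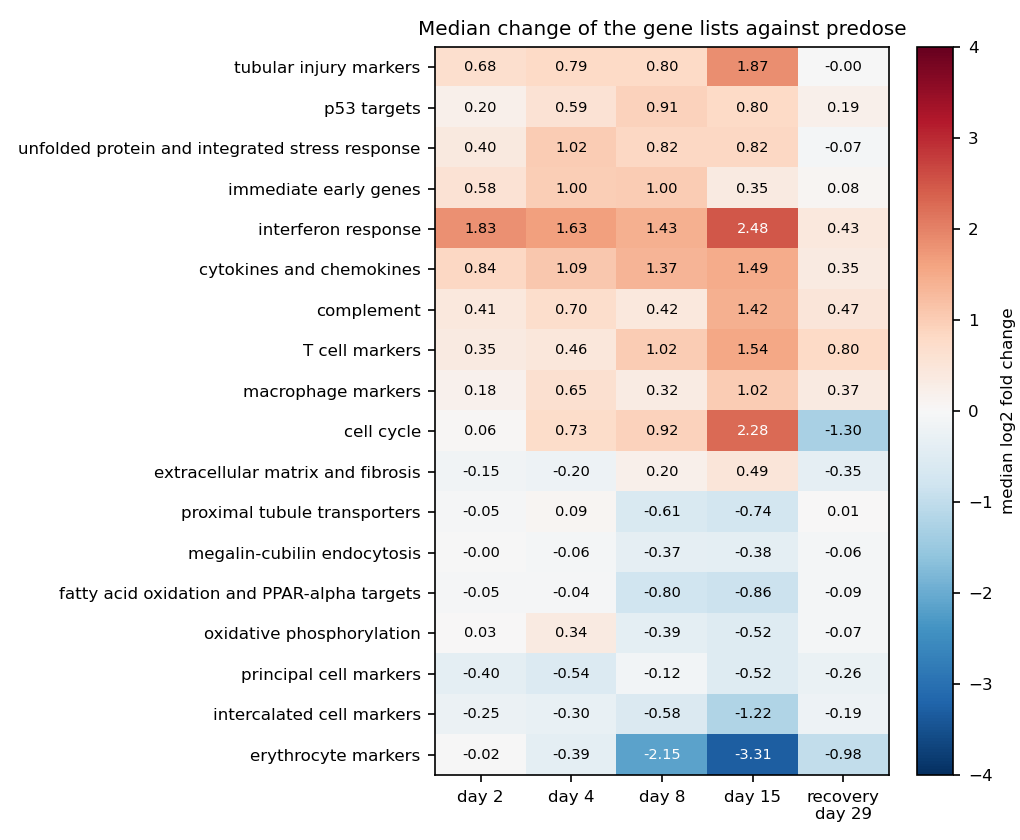
Median log2 change from predose of the measured members of 18 gene lists at each time, both sexes together, in colour from lower (blue) to higher (red). The interferon median was 1.83 at day 2 and 2.48 at day 15, and the cell cycle median moved from 2.28 at day 15 to -1.30 at recovery day 29.

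Successive sampling times were compared to date each change. Between days 2 and 4 Cdkn1a rose 2.87-fold (1.52 ± 0.26 log2, adjusted p = 0.00044) and Bmal1 4.09-fold, while Lrp2 fell by 0.87 ± 0.16 log2 and Cubn by 0.79 ± 0.20 log2. Havcr1 changed by 0.63 ± 0.38 log2 (adjusted p = 0.226). Of 17 genes of the unfolded protein response 10 rose and none fell, 12 when adjusted over the list alone (camera adjusted p = 8.7e-06, and adjusted p = 0.524 with an estimated correlation). In all 2629 genes passed, 1906 higher and 723 lower, all 12 arrays having been scanned on the same day. Leaving out replicate 3 of the day 4 females gave 1654, normexp 411, and a fit to these groups alone 594. Between days 4 and 8 Havcr1 rose 5.19-fold and Cdkn1a 4.61-fold, whereas 21 of 24 fatty acid oxidation genes and 21 of 24 oxidative phosphorylation genes fell, with none higher. Those lists passed camera at adjusted p = 1.3e-05 and 0.00047, and gave adjusted p = 0.608 and 0.845 with an estimated correlation. In all 6496 genes passed, 2075 higher and 4421 lower, and normexp called 3490. Between days 8 and 15 Lcn2 rose 6.03-fold (2.59 ± 0.17 log2, adjusted p = 7.8e-11), Havcr1 5.51-fold and Spp1 5.08-fold, and Cdkn1a changed by -0.34 ± 0.26 log2 (adjusted p = 0.356). Of 18 injury markers 15 rose and none fell (camera adjusted p = 4.2e-12, and adjusted p = 0.0423 with an estimated correlation). Of 23 cell cycle genes 19 rose and none fell (camera adjusted p = 2.1e-10, and adjusted p = 0.113 with an estimated correlation). Here 2926 genes passed, and normexp called 771. Days 4 and 15 shared 1 scan day and day 8 had another, so the comparisons with day 8 hold any effect of scan date. Day 15 minus day 4, within 1 scan day, gave medians of 1.37 for injury markers, 1.22 for the cell cycle, -0.914 for fatty acid oxidation and -0.808 for oxidative phosphorylation. Camera called all 4 (adjusted p = 5.5e-08, 3.4e-12, 1.3e-09 and 8.2e-07), and with an estimated correlation none passed (adjusted p = 0.1105, 0.1105, 0.1105 and 0.316). Day 15 minus day 2, within the same scan day, gave medians of 1.26, 2.06, -0.798 and -0.547 for these lists. With an estimated correlation camera called the first 3 there (adjusted p = 0.033 each) and not oxidative phosphorylation (adjusted p = 0.292).

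Each sex was also tested against its own predose rats within the same model of 12 groups (n = 3 rats per group). In females 146, 2213, 3231, 2542 and 233 genes passed at days 2, 4, 8 and 15 and recovery day 29, and in males 252, 3037, 1916, 3629 and 465. These counts were unstable. Leaving out single arrays gave 60 to 180 genes in females and 73 to 1224 in males at day 2, 985 to 2361 and 1152 to 4311 at day 4, 1125 to 1474 in males at day 8, and 113 to 204 and 258 to 323 at recovery day 29. The highest male counts came without replicate 3 at day 2 and replicate 2 at day 4. Normexp called 9, 323, 329, 1402 and 31 in males and 20, 404, 938, 575 and 12 in females. The changes of all genes in females and males correlated at r = 0.08 at day 2 (Spearman -0.155), 0.69 at day 4, 0.70 at day 8, 0.80 at day 15 and 0.42 at recovery day 29. Called in each sex with the same sign were 61, 1425, 1334, 2006 and 95 genes, where independent calls would share 1.66, 361, 288.7, 419.8 and 5.15. The difference between the sexes in the change from predose passed for few genes: 2 at day 2, none at day 4, 6 at day 8, 1 at day 15 and none at recovery day 29. At an unadjusted p below 0.05, limma gave 2183, 432, 972, 877 and 670 genes in order of time. Camera called list differences between the sexes at day 2, such as medians of 0.79 for cytosolic ribosomal genes (adjusted p = 8.1e-08) and 0.80 for thick ascending limb markers (7.2e-05). Endothelial markers had one of -0.87 (camera adjusted p = 0.00069). None of the day 2 lists held with an estimated correlation, where the lowest adjusted p was 0.2306. At day 8 the sexes differed in the tubular lists. Fatty acid oxidation genes had a male minus female difference of 0.69 in the median (camera adjusted p = 2.2e-17, and adjusted p = 0.0092 with an estimated correlation) and proximal tubule transporters one of 0.49 (adjusted p = 6.7e-06, and adjusted p = 0.0365 with an estimated correlation). Cyp4a8, a fatty acid hydroxylase, changed by -1.72 log2 in females and -0.16 log2 in males (difference 1.56 ± 0.26, adjusted p = 0.0082). Apmap, a membrane protein of adipocytes, changed by -1.39 log2 in females and -0.43 log2 in males (difference 0.97 ± 0.16, adjusted p = 0.0082). With slide as a block, resting on the 1 day 8 male array on the slide of the females, these lists had medians of 0.463 and 0.269 (camera adjusted p = 2.0e-10 and 0.00038), while Cyp4a8 and Apmap did not pass (1.88 and 0.75 log2, adjusted p = 0.083 and 0.458). At day 15 Crtac1, a matrix protein of cartilage, changed by -0.81 log2 in females and 1.97 log2 in males (difference 2.78 ± 0.35, adjusted p = 0.00018). No slide held both sexes at day 2 or day 15, so slide and sex cannot be told apart there. Against the 1 predose female array scanned with day 15, 92.4% of the genes called in males at day 15 had the same sign in females, and 65.9% did at day 2.

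Before dosing the sexes differed in 327 genes, 201 higher and 126 lower in males (n = 3 rats per sex). The dehydrogenase relative Dhrs7l1 was at least 411-fold higher in males, the organic anion transporter Slco1a1 at least 403-fold, Mlc1 at least 140-fold and Slc22a22, a prostaglandin transporter, 213-fold (7.73 ± 0.66 log2, adjusted p = 4.6e-09), and 2 of 2 measured Y-linked genes were higher as well. Higher in females were the aldose reductase relative Akr1b7, at least 41.5-fold, the alcohol dehydrogenase Adh6 (-6.11 ± 0.59 log2, adjusted p = 5.5e-08), the cytochrome P450 Cyp2b21, at least 5.72-fold, and the cannabinoid receptor Cnr1, at least 9.04-fold. Of 19 matrix genes 1 passed, higher in males, and 7 did when adjusted over the list alone, with a median of 0.50 (camera adjusted p = 4.5e-05, and adjusted p = 0.43 with an estimated correlation). Of 23 proximal tubule transporters 2 passed, both higher in males. Normexp called 59 genes, slide as a block 145, and leaving out replicate 1 of the predose females 183.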

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

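The comparison between the sexes, its gene lists and the regrouping of arrays were set beforehand, and the test of targets without a gene symbol was chosen after the result was seen.

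The change from predose differed between the sexes in 2 genes at day 2, 6 at day 8 and 1 at day 15, each by a test of the difference itself. At day 2 these were Cygb, a globin of connective tissue cells (0.49 log2 in females, -0.75 in males, difference -1.24 ± 0.20, adjusted p = 0.0172), and the receptor phosphatase Ptpru (1.12 and -0.79, difference -1.91 ± 0.34, adjusted p = 0.0302). The day 2 calls were unstable: leaving out single arrays gave between 0 and 731 genes, the most without replicate 3 of the day 2 males. Under normexp the Ptpru difference turned to 0.65, and no gene passed at days 2, 8 and 15. At day 8 the 6 genes were Cyp4a8, Apmap, the cyclin Ccne1, the cytokine Ctf1, Hap1 and the olfactory receptor Or52r1, and at day 15 the gene was Crtac1. For these counts the additive effects of sex and of time were first taken out of the values of the compared arrays. The sex labels were then regrouped within each time. The highest other count was 2 at day 2 (2 of 100 splits reached it, the real one included), 2 at day 8, and 1 at day 15 (4 of 100 splits). At days 2 and 15 another grouping thus reached the real count, so chance is not excluded for these 2 and 1 genes. At day 8 no other of the 100 splits reached 6. These shares were not adjusted over the times compared. At day 4 and recovery day 29 no gene passed in limma (432 and 670 at an unadjusted p below 0.05, beside 2183, 972 and 877 at days 2, 8 and 15), so all 100 of 100 splits reach a count of 0 by construction (highest other count 1), and regrouping says nothing about chance there.

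At day 8 a difference between the sexes was found in 3 gene lists that held with an estimated correlation. The median male minus female difference was 0.692 for fatty acid oxidation (adjusted p = 0.0092), 0.485 for proximal tubule transporters (adjusted p = 0.0365) and -0.587 for smooth muscle and mesangial markers (adjusted p = 0.0401). Females and males of day 8 were scanned on the same day, but slide went with sex: the 3 females and 1 male lay on 1 slide and the other males on another. With slide as a block, resting on that male, the medians were 0.463, 0.269 and -0.537 (camera adjusted p = 2.0e-10, 0.00038 and 0.0033), while none of the 6 genes passed in limma (adjusted p from 0.083 to 0.458). At days 2 and 15 no slide held both sexes, so slide and sex cannot be told apart for their genes. Sex, with what goes with it in body weight or drug exposure, stays open as an untested explanation.

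Targets without a gene symbol, which the comparisons of the report leave out and 1 alternative includes, held a signal against the predose controls. Of 15084 such targets 4393 passed at day 15, 1837 higher and 2556 lower (29.1%), beside 4630 of 10977 named genes.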

How the results depend on the processing

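Targets without a gene symbol and the removal of the day 2 and day 4 male arrays of weakest signal were chosen after the results were seen, and all other alternatives were set beforehand.

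Quantile normalization and the authors' log2 table kept every count within 1.5 times. Normexp changed the signal used (the median of the spot), the background correction and an offset of 50 together. It kept 372 of 488 values of named genes on their side of the threshold with the same direction and lost 114, while scan date as a block kept 172 of 258 and lost 84. Normexp called 53, 2012, 1885, 2099 and 76 genes at days 2, 4, 8 and 15 and recovery day 29, 20, 404, 938, 575 and 12 in females, 9, 323, 329, 1402 and 31 in males, 411, 3490, 771 and 1889 between successive times, and 59 between the sexes at predose. It called 0 sex differences at days 2, 8 and 15 and left 43 shared calls of recovery day 29 and day 15. Signal over background limited which genes could be tested: probes well above background on all arrays, fewer genes by construction, gave 45 of the 96 largest changes, 149 genes in females at recovery day 29 and 1 sex difference at day 2. No filter gave 6 sex differences at day 2 and 2 at recovery day 29, the mean of the probes 6 at day 2 and 3 at day 8, and eBayes with trend and robust 1 at day 2 and 1 at recovery day 29. The cause was not tested.

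The replicate numbers do not pair the rats, and as a block they moved 1 count by over 1.5 times, the sex differences at day 2, to 1. Of 488 values of named genes 6 lost and 1 gained a call under that block, and of 570 list tests 1 and 3 did. Scan date as a block called 21, 96 and 1340 genes at days 2, 4 and 15, 33, 192 and 1072 in females and 11, 13 and 865 in males, and 1 sex difference at recovery day 29. It rests on 1 predose female array, so fewer arrays carry the estimate by construction. It could not be fitted for day 8 and recovery day 29 against predose or for successive times that differ in scan day, where a random block (correlation -0.04) gave 1371 genes at recovery day 29 and left the other counts within 1.5 times. Slide as a fixed block could be fitted for the day 2 males (11 genes), the sexes at predose (145) and 3 sex differences (1 at recovery day 29). As a random block slide had a negative correlation of -0.189, which narrows the errors by construction. It called 1361 genes at day 2 and 2820 at recovery day 29, 622, 3368, 4923 and 629 in females at days 2, 4 and 8 and recovery day 29, 3092, 2916 and 1344 in males at days 2 and 8 and recovery day 29, 4833 between days 2 and 4, 5187 between days 8 and 15, 1831, 56, 17 and 2 sex differences at days 2, 8 and 15 and recovery day 29, and 1519 shared calls. A fit to the compared groups alone, with fewer arrays by construction, called 19 genes in females and 42 in males at day 2, 70 in males at day 4, 594 between days 2 and 4, and 119 in females and 255 in males at recovery day 29. It gave 0 sex differences at days 2 and 8, 12 at day 15 and 1 at recovery day 29.

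With targets without a symbol, more targets by construction, 10393, 8515, 8811 and 1719 passed at days 4, 8 and 15 and recovery day 29, 4545, 5593, 4027 and 442 in females, 387, 6650, 3108 and 6770 in males at days 2, 4, 8 and 15, 5768, 14143, 5651 and 8333 between successive times, 506 between the sexes at predose, 4 and 2 sex differences at days 2 and 15, and 851 shared calls. Without the 2 weakest male arrays 116 genes passed in males at day 2 and 1451 at day 4, with 0, 1 and 21 sex differences at days 2, 4 and 8.

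Directions turned in few cases, and the cause was not tested. Ptpru, with a sex difference of -1.91 at day 2, was 0.65 under normexp. Slc34a1 fell by 0.36 log2 between days 4 and 8 but was 0.20 under quantile normalization and 0.23 in the authors' table. The olfactory receptor Or9s14 fell by 1.75 log2 at day 2 and 1.93 at day 4 but was 0.60 and 0.42 with scan date as a block. For lists, camera's direction against all other genes turned, and the median could keep its sign. The cytosolic ribosomal list between days 4 and 8 went from a median of -0.565 to 0.00058 under quantile normalization and -0.0032 in the authors' table, and its sex difference at day 4 from 0.354 to -0.053 without the 2 weakest arrays. The sex difference of the oxidative phosphorylation list at day 2 went from 0.537 to 0.31 under normexp, -0.0086 under quantile normalization and -0.019 in the authors' table. Under normexp the sex differences of T cell and B cell markers at recovery day 29 went from 0.408 and 1.043 to -0.45 and -0.36.

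Leaving out each array in turn gave 179 to 302 genes at day 2 and 1654 to 3815 between days 2 and 4, each lowest without replicate 3 of the females of the later day. It gave 60 to 180, 985 to 2361 and 113 to 204 in females at days 2 and 4 and recovery day 29, each lowest without replicate 3 of that group. It gave 73 to 1224, 1152 to 4311, 1125 to 1474 and 258 to 323 in males at days 2, 4 and 8 and recovery day 29. The male extremes came without day 2 replicates 1 and 3, day 4 replicates 3 and 2, day 8 replicates 2 and 1, and recovery replicates 1 and 3. The sexes at predose gave 183 (without female replicate 1) to 243. Sex differences ran from 0 to 731, 0 to 1, 4 to 18, 1 to 2 and 0 to 9 in order of time, with 18 without replicate 2 of the day 8 females and 9 without replicate 1 of the recovery females. All other counts stayed within 1.5 times.

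The arrays that moved a count by over 1.5 times were these. In females at day 2, predose replicates 1 and 2 gave 88 and 78 when left out and day 2 replicates 2 and 3 gave 85 and 60. At day 4 these predose arrays gave 1257 and 1123, and day 4 replicates 1 and 3 gave 1142 and 985. At recovery day 29 the 3 predose arrays gave 135, 126 and 136, and recovery replicates 2 and 3 gave 135 and 113. In males at day 2 the 3 predose arrays gave 131, 78 and 119 and the 3 day 2 arrays 73, 115 and 1224. At day 4 predose replicate 2 gave 1543 and day 4 replicate 3 gave 1152. At day 8 predose replicates 1 and 3 gave 1138 and 1163 and day 8 replicates 2 and 3 gave 1125 and 1229. At recovery day 29 the 3 predose arrays gave 272, 262 and 268, and recovery replicates 1 and 2 gave 258 and 266. Between the sexes at predose, female replicate 1 gave 183 and male replicates 1 and 3 gave 193 and 217. Sex differences at day 2 went to 0 without predose female 2, predose male 2, day 2 females 2 and 3 or day 2 male 1, and to 1 without predose male 1, day 2 female 1 or day 2 male 2. At day 4 predose female 2 and day 4 male 3 gave 1, at day 8 day 8 male 3 gave 10, at day 15 predose female 2 and day 15 female 3 gave 2, and at recovery day 29 predose females 1 and 3 and predose male 2 gave 1.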

Other observations

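The limma comparisons of the report and their list tests were set beforehand. The tests of the bright cell cycle genes and of clock output genes, and the regroupings of the arrays, were chosen before their results were seen. All other tests in this part were chosen after.

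Of 9 thick ascending limb markers 7 fell at day 15 and none rose, with a median of -0.75 (camera adjusted p = 0.0012, and adjusted p = 0.0916 with an estimated correlation). Umod, the most abundant urinary protein of that segment, fell by 0.45 ± 0.11 log2. Of 24 oxidative phosphorylation genes 16 fell at day 15 and none rose, 19 when adjusted over the list alone, with a median of -0.52 (camera adjusted p = 7.0e-05, and adjusted p = 0.303 with an estimated correlation). Of 19 NRF2 targets of oxidative stress 8 fell and 1 rose at day 15, with a median of -0.48 (camera adjusted p = 0.0288, and adjusted p = 0.303 with an estimated correlation), and Nqo1, an established member, changed by -0.27 ± 0.22 log2 (adjusted p = 0.34). The calcium-binding protein S100g fell by 2.41 ± 0.27 log2 at day 8 and was 6.11-fold higher at recovery day 29 than at day 15. Heat shock gene Hspa1a was 6.35-fold higher at day 4 (2.67 ± 0.31 log2, adjusted p = 5.9e-07).

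Clock genes moved apart from injury genes. An index of 2 genes that rose (Bmal1, Npas2) minus 5 that fell (Dbp, Per2, Per3, Nr1d2, Tef), chosen after their values were seen, was -2.21 ± 0.71 (SD, n = 6) at predose, -2.00 at day 2, 1.46 at day 4, 2.33 at day 8, 1.63 at day 15 and 2.44 at recovery day 29. Scan date is argued against as the whole cause for days 4 and 15 by the whole clock list, written beforehand, within 1 scan day. Of its 13 genes 2 rose and 7 fell between days 2 and 4, and 2 rose and 8 fell between days 2 and 15. With an estimated correlation camera called neither (adjusted p = 0.524 and 0.337). All 7 arrays of predose and day 2 scanned with days 4 and 15 had an index of -1.06 or lower. That was nearer to the other predose arrays (mean -2.44) than to days 4 and 15 (mean 1.54), but the choice of the index genes favours such a result. A part is not excluded, as the predose array among them had the highest index of the 6. For day 8 and recovery day 29, with 0 predose arrays on their scan day, scan date and time cannot be told apart. A change that follows tubular injury was tested on the 10 members of the clock list called between days 2 and 15, chosen without the recovery arrays. Their mean shift from predose at recovery day 29 was 97.6% of that at day 15 while the injury list stood at -0.00. The standard error, 14.5 over genes, leaves out the spread between rats. For the mean of these genes only, this argues against such a change unless scan date moved the recovery arrays. Single genes moved both ways after day 15: Bmal1, Npas2 and Per3 further from predose, and Nr1d1, Tef and Bhlhe40 back, each called in limma. Of the 10 genes 3 lay nearer to predose than to day 15. Tissue taken at another time of day may be a candidate explanation, which no value decides. A set of 3 clock output genes outside the list, named before the test, had a median of -0.87 at recovery day 29. That was at the 0.13 percentile of 10000 random sets, with Wee1 and Tspan4 called and Tsc22d3 not. These genes were named because they peak near Dbp, which had fallen. Any cause that moved the clock genes could lower them too, so their fall does not favour time of day. Random sets also leave out the correlation between clock outputs. The age of the rats stays open as untested.

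Cell cycle genes lay below predose at recovery day 29, and dim probes are argued against as the cause. The 14 members well above background on all 36 arrays had a median of -0.9633, and 8 of them were called lower. Scan date cannot be told apart from recovery: the list was higher at day 8, scanned on the same day (median 0.9153), but no predose array was. Recovery day 29 rats were older than predose rats, and a lower rate of cell division with age may account for the fall, which no age-matched saline group tests.

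The breadth of the day 4 calls was set against technical causes, because signal was weakest then and brighter genes moved more, with a median of 0.29 in the brightest of 5 equal classes of genes. Scaling by the percentile is argued against as the whole cause, since quantile normalization gave 4511 calls, 3990 of them among the 4800 with the same sign, with a median of 0.04 in that class. The 2 male arrays of weakest signal are too, with 4399 calls without them, 4032 of them among the 4800. For the main axis of spread within groups no value decides: with it in the model 4048 genes were called. That axis had its strongest correlation with the change from predose at day 4 (-0.347), beside -0.177 at day 2, 0.134 at day 8, 0.0843 at day 15 and 0.0737 at recovery day 29. It was taken from the spread of these same arrays, so entering it narrows the errors by construction. Calls rose with it from 4433 to 5195 at day 8 and from 4630 to 5523 at day 15. Scan date and day 4 cannot be told apart for this breadth. Between days 4 and 2, scanned together, 2629 genes were called, but a fit to these groups alone called 594, normexp 411 and leaving out replicate 3 of the day 4 females 1654. When these arrays were regrouped, 5 of 100 splits, the real one included, called as many genes and the highest other count was 3386, so chance is not excluded for it. With scan date as a block, resting on 1 predose female array, 96 genes were called at day 4. Against that array 95.4% of the genes called in males had the same sign in females. Splits that call more than the real one point to a structure of the samples, and 17.6% of the spread within groups lay on 1 axis that the day 2 and day 4 males carried most.

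Regrouping the arrays argued against chance for each time against predose with both sexes together. Of 100 splits, from 200 possible ones, only the real one reached its count. These shares were not adjusted over the comparisons. The real and highest other counts were 292 and 123 at day 2, 4800 and 2769 at day 4, 4433 and 2160 at day 8, 4630 and 2610 at day 15, and 902 and 112 at recovery day 29. The real split alone also reached its count between days 4 and 8 (6496 and 5274), days 8 and 15 (2926 and 1503), and day 15 and recovery day 29 (4168 and 1971). Within 1 sex only 10 splits exist, too few for a share under 0.05. In females the real and highest other counts were 146 and 2, 2213 and 1, 3231 and 2, 2542 and 2, and 233 and 3 in order of time. In males they were 252 and 1, 3037 and 429, 1916 and 0, 3629 and 1, and 465 and 1. Between the sexes at predose they were 327 and 0.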
